A study of Mus musculus with 9 samples.

How the data were processed

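RNA from a mouse CD8-positive dendritic cell line was sequenced in 9 libraries, 3 from unstimulated cells, 3 from cells stimulated for 6 h with a class B CpG oligonucleotide and 3 from cells stimulated for 6 h with high molecular weight poly(I:C). The labels give the CpG dose as 1 mM, and whether that unit is right could not be checked. They give the poly(I:C) dose as 5 μg/ml in the treatment protocol and in milligrams per ml elsewhere, and this difference could not be settled. Total RNA was extracted with Tri Reagent and libraries were made with a TruSeq RNA kit. The series text also names a shorter stimulation, which was not analysed here.

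The authors deposited raw counts, with 1 file per library that lists the number of reads for each of 23420 gene symbols and ends in 5 HTSeq summary lines. The submitters' processing notes name TopHat2 2.0.7, Cufflinks 2.0.2 and HTSeq 0.6.0 and the mouse build mm10. The gene annotation, the strand setting and any filter are not given in the sources used here. The values were whole numbers with a different total in every library, and no pair of libraries was identical. Gene symbols are those of the files. Positions of the genes named are those of the RefSeq annotation of GRCm38, the build also called mm10, and all 644 genes looked up had a position there.

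Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with too few reads were removed with filterByExpr, at its minimum count of 10 and minimum total of 15, which left 11282 genes. Libraries were scaled by TMM factors. A quasi-likelihood model with 1 mean per group was fitted robustly to all 9 libraries, and the 3 contrasts between groups were tested with glmQLFTest. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Fold changes are given on the log2 scale with their standard error, and levels as CPM, which are read counts scaled to a common library size by the TMM factors. All tests were two-sided. Where a group had no read of a gene, its fold is a lower bound computed against 3 reads over the group. Where a group had 1 to 3 reads, the ratio of normalised read totals is given with a 95% interval for counting error. Reads without molecular identifiers are not independent molecules, so these intervals and limits cover counting error alone.

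Gene lists, the rule for the genes named, the tests and most alternatives were written down before the data were examined. There were 22 lists of programmes, namely interferon genes, antiviral interferon-stimulated genes, interferon-induced GTPases, inflammatory cytokines, chemokines, NF-kB targets, dendritic cell maturation, MHC class I and class II presentation, cDC1 identity, pattern recognition, SOCS family, AP-1 and immediate early genes, glycolysis, oxidative phosphorylation, cholesterol synthesis, cell cycle, ribosomal proteins, apoptosis, ER stress, antioxidant genes and lysosome. Histones and mitochondrial RNA were listed as signs of RNA quality. Markers of T cells, B cells, NK cells, macrophages and monocytes, neutrophils, plasmacytoid dendritic cells, cDC2 cells, erythroid cells and stromal cells were listed as checks for other cells. The 28 lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, on log2 CPM with a prior count of 2, and adjusted over the lists of a comparison. Camera was also run with an estimated correlation. The test fry asks whether the genes of a list move, on balance, 1 way, without comparing them with other genes.

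The genes named were 14 anchor genes, the 8 largest rises and the 6 largest falls of each comparison, and up to 3 changed members per list. The largest changes were taken among genes with a mean CPM of at least 10 in the higher group, at least 10 reads in each group and no overlap between the libraries of the groups, leaving out predicted genes. Any other gene named was chosen after its values were seen, as an example of its list.

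The alternatives were RLE scaling, scaling by library totals, DESeq2 1.42.0, limma voom, no filter on low counts, a mean CPM of at least 5, only the 6 libraries compared, the replicate number as a block, counts thinned to the smallest library, an adjusted p under 0.01, glmTreat against a fold of 2, and leaving out each library in turn. Overlap between the responses was set beside 30 simulated data sets in which both stimulated groups were unchanged but shared the controls. The procedure was tested on counts simulated from the fitted mean and spread of each gene and the real library sizes. In these, 200 genes were given known changes, as many up as down. The procedure recovered 68% to 72% of genes changed 1.3-fold, 80% to 84% at 1.5-fold, 88% to 94% at 2-fold and 98% to 100% at 4-fold, and 4.9% to 6.1% of its calls were false. Far fewer genes changed there than were called in the data, and rises and falls were balanced. These shares therefore leave out errors of scaling and need not hold in the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for reading, positions and figures.

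Gene reads per library ranged from 7005596 to 20685769. A count of 0 allows a level of up to 0.145 to 0.428 CPM, depending on the library. The 12138 genes below the count filter were not tested. The symbols Ifna15, Ifna16, Rnf213, Rab7b, Ly6g, Hbb-bs, Hbb-bt and the 12 mitochondrial transcripts were not analysed here because the files hold no such symbol. Genes with near-identical copies, such as the Bcl2a1 family, the interferon alpha genes, Ifnl2 and Ifnl3, the Gbp and Tgtp genes and the H2 genes, can share reads, so their counts are less certain. With 3 libraries against 3, an exact permutation test of a single gene cannot give a p below 0.10, so calls rest on the model. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these libraries.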

Results

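Gene expression was measured by RNA sequencing in a mouse CD8-positive dendritic cell line that the labels trace to the spleen. Dendritic cells of this kind take up antigen and present it to T cells. There were 3 libraries of unstimulated cells, 3 of cells given CpG and 3 of cells given poly(I:C). CpG oligonucleotides are ligands of the endosomal receptor Tlr9, and poly(I:C) is a synthetic double-stranded RNA that Tlr3 and the cytosolic receptor Ifih1 recognise. The series title sets inflammatory against antiviral programmes, so the comparisons ask which genes each ligand changed and in which genes the ligands differed.

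Reads on genes numbered 8440666, 20685769 and 10363397 in the unstimulated libraries, 10071267, 13179392 and 10569138 with CpG, and 7005596, 8425607 and 12186741 with poly(I:C). Between 58.49% and 59.37% of the reads in each file fell on no gene. Across genes, which are not independent replicates, log2 levels of libraries within a group correlated at r = 0.992 to 0.995. Unstimulated libraries correlated with CpG libraries at 0.869 to 0.872 and with poly(I:C) libraries at 0.86 to 0.865, and the stimulated groups with each other at 0.946 to 0.95. The first principal component held 71.8% of the variance and separated unstimulated from stimulated cells. The second held 22.7% and separated CpG from poly(I:C). Levels are mean CPM, read counts scaled to a common library size, over 3 libraries per group, positions are on GRCm38, and errors after ± are standard errors on the log2 scale unless named as SD.

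With poly(I:C), antiviral and chemokine genes were among the largest rises over unstimulated cells, taken among genes with at least 10 reads in each group. Ccl5, a chemokine that attracts T cells, rose by 10.09 ± 0.10, from 1.92 to 2199 CPM (chromosome 11, 83525778 to 83530518). Rsad2, which makes the antiviral protein viperin, rose by 10.01 ± 0.11 to 697.9 CPM (chromosome 12, 26442743 to 26456452). Cxcl10, an interferon-induced chemokine, rose 522-fold, from 4.669 to 2369 CPM (chromosome 5, 92346638 to 92348889). Il27, a subunit of interleukin 27, rose by 9.65 ± 0.14, and Irg1, the enzyme that makes itaconate, by 8.92 ± 0.08.

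Of 11282 genes tested, 8363 changed with poly(I:C), 4093 higher and 4270 lower. At least 2-fold changes numbered 1594 higher and 1441 lower, and at least 10-fold changes 352 and 75. In 75.1% of the genes the 3 libraries of each group did not overlap, against 10% by chance. The other largest rises were of Slfn1 (8.76 ± 0.16), Ifit1 (8.65 ± 0.11) and Gbp2 (8.36 ± 0.11), all known as interferon-induced. The largest falls were of the acetyl-CoA synthetase gene Acss1 (-6.26 ± 0.15), the chemokine receptor gene Cxcr3 (-6.05 ± 0.23), the natriuretic peptide receptor gene Npr3 (-5.55 ± 0.25), the kinase gene Map2k6 (-5.34 ± 0.19), the amino acid transporter gene Slc43a2 (-4.91 ± 0.14) and Cd244 (-4.87 ± 0.15).

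All 58 tested antiviral interferon-stimulated genes rose with poly(I:C), each at least 2-fold, with a median of 4.50 (camera adjusted p = 1.83e-25, and adjusted p = 0.0204 with an estimated correlation). All 58 also rose when adjusted over the list alone. Among them were Ifit1, Rsad2 and Cmpk2, a nucleotide kinase (7.64 ± 0.11). All 16 interferon-induced GTPases rose, with a median of 5.39, or 4.82 with 4 genes of 2 or 3 reads at the low end of their counting intervals (camera adjusted p = 5.99e-09). Gbp5, a guanylate-binding protein, had 2916 reads against 2 in unstimulated cells, a ratio of 2690 (95% counting interval 745 to 22200). The 3 interferon genes tested rose (camera adjusted p = 0.0208, and adjusted p = 0.108 with an estimated correlation). Ifnb1, which encodes interferon beta, had 279 reads against 2, a ratio of 258 (70.7 to 2140; chromosome 4, 88522025 to 88522794). Ifnl2 and Ifnl3, interferon lambda genes with near-identical copies, had no read in unstimulated cells and were at least 122-fold and at least 67.7-fold higher. The list median was 8.69, or 6.93 with these genes at their bounds. The interferon alpha genes in the files had no read in any group.

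Among 17 inflammatory cytokines, 15 rose, Tgfb1 fell (-0.68 ± 0.05) and Il12a did not pass, with 1 read against 0 (camera adjusted p = 2.21e-06). Il12b, the shared subunit of interleukins 12 and 23, rose by 7.20 ± 0.13 to 318.5 CPM, Il6 by 7.06 ± 0.10 and Tnf by 6.41 ± 0.08. Il10, a cytokine that restrains inflammation, rose by 2.30 ± 0.59, to 0.767 CPM. Of 17 chemokines, 16 rose and Ccl6 fell (-0.93 ± 0.13), with a median of 4.35 (camera adjusted p = 5.78e-07). Cxcl11 had no read in unstimulated cells and was at least 320-fold higher. Of 36 NF-kB targets, 33 rose, 1 fell and 2 did not pass (camera adjusted p = 3.14e-13), among them Gadd45b (6.36 ± 0.10) and the signalling adaptor gene Traf1 (5.78 ± 0.07). Sod2 was the member that fell (-0.22 ± 0.06). Dendritic cell maturation genes rose in 20 of 21 cases (camera adjusted p = 1.51e-09). Ccr7, the receptor that guides dendritic cells to lymph nodes, rose by 7.47 ± 0.16, the costimulatory genes Cd40 by 4.38 ± 0.08 and Cd86 by 1.75 ± 0.05, and Cd274, which encodes PD-L1, by 5.67 ± 0.09.

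MHC class I presentation genes rose in 16 of 21 cases and fell in 4, with a median of 1.22 (camera adjusted p = 0.000313). The class I transactivator gene Nlrc5 rose by 2.87 ± 0.05 and the chaperone gene Calr fell (-0.57 ± 0.05). MHC class II presentation genes fell in 12 of 16 cases and rose in 4, with a median of -0.65 (camera adjusted p = 0.019, and adjusted p = 0.265 with an estimated correlation). H2-DMb1, a peptide loading subunit, fell (-2.40 ± 0.06) and so did Ciita, the class II transactivator (-1.75 ± 0.05). Genes of cDC1 identity, the type of dendritic cell that carries Cd8a in the spleen, fell in 18 of 26 cases and rose in 8 (camera adjusted p = 0.0357, and adjusted p = 0.291 with an estimated correlation). Cxcr3 and Sept3 (-2.72 ± 0.08) fell, while Cd8a rose by 3.46 ± 0.05 and the chemokine receptor gene Xcr1 by 1.32 ± 0.05. Tlr3 fell (-0.37 ± 0.07) from 1322 to 1026 CPM. Beside these lists, markers of macrophages and monocytes rose in 8 of 12 cases and fell in 4 (camera adjusted p = 0.23, but called upward with library totals in place of TMM at 0.044, range over all camera alternatives 0.044 to 0.583), and their summed level was 607.4 ± 11.5 (SD) CPM by library totals in unstimulated cells and 262.3 ± 2.05 (SD) with poly(I:C). Lyz2, their most abundant gene, fell (-1.83 ± 0.06), as did the growth factor receptor gene Csf1r (-2.56 ± 0.13).

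Pattern recognition genes rose in 25 of 33 cases and fell in 8 (camera adjusted p = 0.00395), with Tlr9 up by 2.45 ± 0.06 and Tlr12 down (-2.72 ± 0.06). Apoptosis genes rose in 18 of 26 cases and fell in 3 (camera adjusted p = 3.04e-05), among them the death ligand gene Tnfsf10 (6.51 ± 0.29) and the inflammatory caspase gene Casp4 (6.02 ± 0.25), while Casp6 fell (-2.49 ± 0.11). AP-1 and immediate early genes rose in 18 of 26 cases and fell in 6 (camera adjusted p = 0.00444, and adjusted p = 0.223 with an estimated correlation), with the nuclear receptor gene Nr4a3 up by 7.88 ± 0.14. Cell cycle genes fell in 27 of 40 cases and rose in 9, or 10 adjusted over the list alone (camera adjusted p = 0.0128). The mitotic gene Cdc20 fell (-1.22 ± 0.07) and the cyclin gene Ccnd2 rose by 3.15 ± 0.06. Lysosome genes fell in 18 of 25 cases and rose in 5 (camera adjusted p = 0.00664, and adjusted p = 0.142 with an estimated correlation), with Psap, the precursor of saposins, down (-1.49 ± 0.05) and the cholesterol transporter gene Npc2 up by 2.29 ± 0.05. Cholesterol synthesis genes rose in 19 of 24 cases and fell in 5 (camera adjusted p = 0.0208, and adjusted p = 0.142 with an estimated correlation), with Dhcr7 down (-1.69 ± 0.07).

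Apart from the stromal markers, the lists that follow were not called with poly(I:C). SOCS family genes rose in 4 and fell in 3 of 7 cases, with Socs3 up by 4.81 ± 0.16. Glycolysis genes rose in 10 and fell in 7 of 23 cases, and their median of -0.05 and mean of 0.14 differed in sign, the mean turning to -0.23 with library totals in place of TMM. Oxidative phosphorylation genes split into 10 higher and 10 lower of 35. Ribosomal protein genes rose in 5 of 33 cases and 28 did not pass, and their mean of 0.07 turned to -0.30 with library totals in place of TMM. ER stress genes fell in 11 and rose in 5 of 21 cases. Antioxidant genes rose in 8 and fell in 3 of 15 cases, or 4 adjusted over the list alone, with Irg1 and the autophagy adaptor gene Sqstm1 (1.46 ± 0.06) highest. Of 6 histones, 3 fell and 3 did not pass. Of the other cell markers, 3 T cell genes rose, with Cd4 up by 0.80 ± 0.15, 3 of 4 plasmacytoid dendritic cell genes rose, with Tcf4 up by 0.95 ± 0.08, and cDC2 genes split into 2 higher and 2 lower. With library totals the T cell list (adjusted p = 0.0284, range 0.0284 to 0.184) and the plasmacytoid list (0.0414, range 0.0414 to 0.236) were called upward. The median of -0.31 and mean of -0.51 of the cDC2 list stood against an upward fry direction. The single tested B cell gene, Ms4a1, rose by 1.66 ± 0.38 and the single NK cell gene, Klrk1, by 2.00 ± 0.06. All 3 stromal genes rose (camera adjusted p = 0.0357, and adjusted p = 0.142 with an estimated correlation), led by the endothelial cadherin gene Cdh5 (4.51 ± 0.08, from 5.41 to 124 CPM). Neutrophil, erythroid and mitochondrial lists had no tested member. Only 3 of 12 T cell, 4 of 10 plasmacytoid, 4 of 10 cDC2 and 3 of 8 stromal markers in the files were tested. The untested markers of these lists had at most 15 reads over a group. Cd3e, Cd209a, Clec10a and Col3a1 had no read in any group and Siglech had 1.

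Scaling by library totals moved the median of all genes by -0.37, relative to which changes are given, and called 2447 genes higher and 6764 lower, 26.6% upward instead of 48.9%. It ended the calls of MHC class II (mean -1.21 against -0.84 with TMM, adjusted p = 0.0537, range over all camera alternatives 0.0152 to 0.265), cDC1 identity (mean -1.01 against -0.64, adjusted p = 0.178, range 0.0259 to 0.291) and lysosome (mean -0.77 against -0.40, adjusted p = 0.0523, range 0.0046 to 0.142), whose means moved down with all genes, and of cholesterol synthesis (0.141, range 0.0195 to 0.142), whose mean turned from 0.27 to -0.09.

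**Figure D1:**
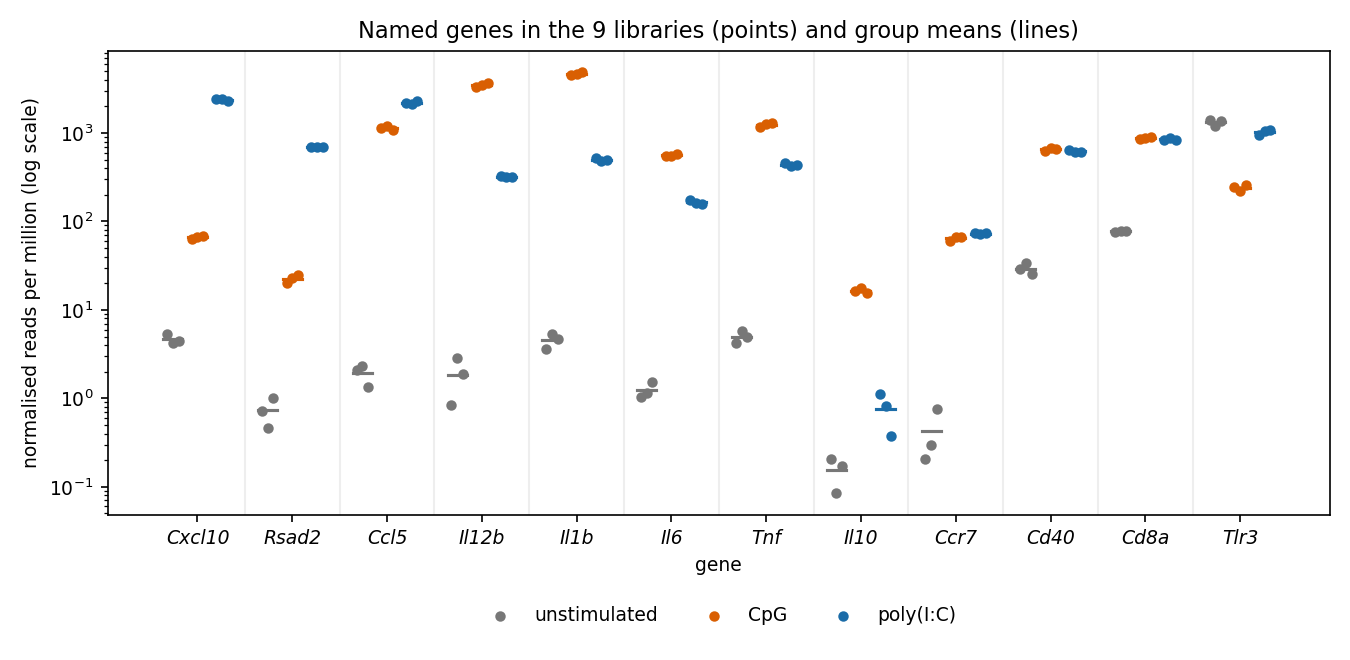
CPM (vertical log axis) of 12 named genes in the 9 libraries. Points are the 3 libraries of each group and lines the group means. Cxcl10 averaged 2369 with poly(I:C) and 66.59 with CpG, while Il12b averaged 318.5 and 3471.

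With CpG, inflammatory cytokine and chemokine genes were among the largest rises over unstimulated cells. Il12b rose by 10.65 ± 0.12, from 1.857 to 3471 CPM (chromosome 11, 44400063 to 44414677). Il1b, which encodes interleukin 1 beta, rose 991-fold, from 4.53 to 4706 CPM (chromosome 2, 129364569 to 129371164). The chemokine genes Ccl4 and Ccl5 rose by 9.80 ± 0.09 and 9.13 ± 0.09, Ccl3 by 8.85 ± 0.09, Il6 by 8.83 ± 0.09, and Tnf by 7.91 ± 0.08.

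With CpG 8245 genes changed, 4107 higher and 4138 lower. At least 2-fold changes numbered 1283 higher and 1436 lower, and at least 10-fold changes 343 and 124. The groups did not overlap in 74.5% of genes, against 10% by chance. Il27 (8.81 ± 0.14) and Lad1 (8.38 ± 0.12) completed the largest rises among genes with at least 10 reads in each group. The largest falls were of Acss1 (-7.16 ± 0.15), Npr3 (-6.75 ± 0.26), Pgbd5 (-5.75 ± 0.16), Tchh (-5.69 ± 0.20), Hepacam2 (-5.56 ± 0.11) and the prostaglandin-degrading enzyme gene Hpgd (-5.45 ± 0.20).

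Of 17 cytokines, 15 rose with CpG, Tgfb1 fell (-0.88 ± 0.05) and Lif was not called (0.28 ± 0.17), with a median of 4.62 (camera adjusted p = 3.16e-07). Il10 rose by 6.84 ± 0.25 to 16.48 CPM, and Il12a, the other subunit of interleukin 12, had no read in unstimulated cells and was at least 29.2-fold higher. Of 17 chemokines, 16 rose and Ccl6 fell (-0.39 ± 0.11), with a median of 4.05, or 3.88 with genes at 0 reads at their bounds (camera adjusted p = 2.47e-07). All 36 NF-kB targets rose (camera adjusted p = 1.12e-16), led by Gadd45b (7.63 ± 0.09) and Nfkbiz, an inhibitor-related regulator of NF-kB (7.51 ± 0.08). Maturation genes rose in 18 of 21 cases and fell in 2 (camera adjusted p = 2.47e-07). Ccr7 rose by 7.30 ± 0.16, Cd40 by 4.45 ± 0.07 and Cd86 by 0.92 ± 0.05. Pdcd1lg2, which encodes PD-L2, had 749 reads against 2, a ratio of 504 (139 to 4170).

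Antiviral genes rose with CpG in 56 of 58 cases, or 57 adjusted over the list alone, with a median of 3.07 (camera adjusted p = 1.74e-21). Ifit1 rose by 5.37 ± 0.12 and Rsad2 by 5.06 ± 0.16, and Epsti1 fell (-0.62 ± 0.06). Interferon-induced GTPases rose in 15 of 16 cases with a median of 3.37, or 2.70 with genes of 2 or 3 reads at the low end of their intervals (camera adjusted p = 1.10e-06), Gbp2 by 5.03 ± 0.15. The 3 interferon genes were each called higher, but the list was not (camera adjusted p = 0.253), and its median was 3.58, or 0.84 with genes at their bounds. Ifnb1 had 28 reads against 2, a ratio of 18.8 (4.75 to 163). Ifnl2 and Ifnl3, without a read in unstimulated cells, each stood 1.79-fold above a level of 3 reads over that group. This bound leaves out the counting error of their few reads with CpG, so the calls of these near-identical genes are weak.

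Cholesterol synthesis genes rose with CpG in 20 of 24 cases and fell in 4, with a median of 0.93 (camera adjusted p = 1.55e-05). Hsd17b7 rose by 2.08 ± 0.06 and Pmvk by 1.61 ± 0.06, and Ebp fell (-0.55 ± 0.07). Antioxidant genes rose in 10 of 15 cases and fell in 2 (camera adjusted p = 0.0212, and adjusted p = 0.116 with an estimated correlation), with Irg1 up by 5.47 ± 0.08 and Sqstm1 by 2.32 ± 0.06. AP-1 and immediate early genes rose in 19 of 26 cases and fell in 7 (camera adjusted p = 0.00233, and adjusted p = 0.221 with an estimated correlation), with Ier3 up by 6.45 ± 0.10 and the phosphatase gene Dusp6 down (-2.80 ± 0.08). Apoptosis genes rose in 17 of 26 cases and fell in 6 (camera adjusted p = 0.0212, and adjusted p = 0.0882 with an estimated correlation). The survival gene Bcl2l1 rose by 5.03 ± 0.06 and its opponent Bcl2l11 by 3.76 ± 0.06. Pattern recognition genes rose in 19 of 33 cases and fell in 5 (camera adjusted p = 0.0267, and adjusted p = 0.0882 with an estimated correlation), with the kinase gene Ikbke up by 3.69 ± 0.12, Tlr9 by 1.66 ± 0.06, and Tlr12 down (-3.91 ± 0.06).

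MHC class II presentation genes fell with CpG in 11 of 16 cases and rose in 2, with a median of -0.84 (camera adjusted p = 0.00107, and adjusted p = 0.162 with an estimated correlation). H2-DMa fell (-3.68 ± 0.07), as did Ciita (-3.02 ± 0.06), and the protease gene Lgmn rose by 0.32 ± 0.05. Genes of cDC1 identity fell in 18 of 26 cases and rose in 7 (camera adjusted p = 0.0113, and adjusted p = 0.221 with an estimated correlation). Cxcr3 fell (-7.82 ± 0.26), and so did the receptor genes Tlr11 (-4.74 ± 0.15) and Tlr3 (-2.46 ± 0.07, from 1322 to 239.6 CPM), while Cd8a rose by 3.51 ± 0.05 and Xcr1 by 1.02 ± 0.05. Lysosome genes fell in 16 of 25 cases and rose in 8 (camera adjusted p = 0.0356, and adjusted p = 0.221 with an estimated correlation), with the lipase gene Lipa down (-1.79 ± 0.06). MHC class I genes rose in 11 and fell in 7 of 21 cases (camera adjusted p = 0.233), with Nlrc5 up by 1.73 ± 0.05 and the peptide transporter gene Tap2 down (-1.12 ± 0.05). Beside these lists, cDC2 markers rose in 4 of 4 cases (camera adjusted p = 0.0312, and adjusted p = 0.126 with an estimated correlation), with Irf4 up by 1.66 ± 0.09 and Sirpa by 1.49 ± 0.08. Macrophage and monocyte markers rose in 8 and fell in 4 of 12 cases (camera adjusted p = 0.166, but called upward with library totals at 0.0296, range over all camera alternatives 0.0296 to 0.303), with Cd14 up by 2.61 ± 0.09, and their summed level was 412.5 ± 6.87 (SD) CPM by library totals.

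Among the remaining lists, SOCS family genes rose in 4 and fell in 2 of 7 cases with CpG, with Socs3 up by 7.47 ± 0.12. Glycolysis genes fell in 11 and rose in 6 of 23 cases, with Pfkm down (-2.64 ± 0.16). Oxidative phosphorylation genes split into 10 higher and 10 lower of 35, and cell cycle genes into 13 higher and 21 lower of 40. Ribosomal protein genes rose in 9 of 33 cases, or 7 adjusted over the list alone, and their mean of 0.09 turned to -0.11 with library totals. ER stress genes rose in 9 and fell in 10 of 21 cases, with a median of -0.11, a mean of 0.18 that turned to -0.02 with library totals, a downward camera direction and an upward fry direction. Of 6 histones, 3 fell. Of the other cell markers, 2 of 3 T cell genes and 2 of 4 plasmacytoid dendritic cell genes rose, Ms4a1 rose by 2.44 ± 0.31 and Klrk1 by 0.91 ± 0.07. All 3 stromal genes rose (camera adjusted p = 0.0356, and adjusted p = 0.158 with an estimated correlation), with Cdh5 up by 0.84 ± 0.11. Library totals moved the median of all genes by -0.20 (2817 higher, 5614 lower, 33.4% upward instead of 49.8%) and ended the calls of cDC1 identity (mean -1.23 against -1.03 with TMM, adjusted p = 0.067, range over all camera alternatives 0.0066 to 0.221) and lysosome (mean -0.68 against -0.48, adjusted p = 0.0667, range 0.0293 to 0.221). The call of pattern recognition was lost among genes with a mean CPM of at least 5 (adjusted p = 0.0842, range 0.0153 to 0.0882).

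Set against each other, poly(I:C) gave higher antiviral gene levels and CpG higher levels of several inflammatory cytokines. Cxcl10 was 35.6-fold higher with poly(I:C) (5.15 ± 0.06) and Rsad2 30.8-fold (4.95 ± 0.07). Il12b was lower with poly(I:C) than with CpG (-3.45 ± 0.08), as were Il10 (-4.54 ± 0.23; chromosome 1, 131019845 to 131024970), Il1b (-3.24 ± 0.06), Il6 (-1.78 ± 0.05) and Tnf (-1.50 ± 0.05). Among genes within the limits set for the largest changes, with at least 10 reads in each group, 2 showed the largest differences upward with poly(I:C). These were the semaphorin gene Sema4f (6.00 ± 0.12; chromosome 6, 82911884 to 82939769) and Hopx (5.46 ± 0.21). Cxcl11 fell outside these limits, with 520 reads against 8 with CpG, and differed by 6.43 ± 0.32.

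Between the ligands 6472 genes differed, 3295 higher with poly(I:C) and 3177 higher with CpG. At least 2-fold differences numbered 958 and 509, and at least 10-fold differences 69 and 46. The groups did not overlap in 63.2% of genes, against 10% by chance. Cmpk2 (4.30 ± 0.08), Iqgap2 (4.29 ± 0.13), Arhgap8 (4.24 ± 0.26) and Gbp5 (3.97 ± 0.10) were also among the largest differences upward. Within the same limits, the metalloprotease gene Adamts4 (-4.99 ± 0.17), the interferon lambda receptor gene Ifnlr1 (-4.34 ± 0.18), the sulfotransferase gene Hs3st1 (-3.73 ± 0.12), Unc93a (-3.69 ± 0.19) and the transcription factor gene Ehf (-3.63 ± 0.13) were, with Il10, highest with CpG relative to poly(I:C).

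Antiviral genes were higher with poly(I:C) in 56 of 58 cases, or all 58 adjusted over the list alone, 41 of them at least 2-fold, with a median of 1.21 and a mean of 1.54 (camera adjusted p = 6.55e-21). All 16 interferon-induced GTPases were higher, with a median of 2.07 (camera adjusted p = 1.36e-08). All 3 interferon genes were higher (camera adjusted p = 0.0127, and adjusted p = 0.0978 with an estimated correlation), with Ifnb1 up by 3.76 ± 0.25. Inflammatory cytokines were lower with poly(I:C) in 11 of 17 cases and higher in 5, with a median of -1.23, and the list was not called (camera adjusted p = 0.0591). It was called without CpG replicate 2 (adjusted p = 0.0303), poly(I:C) replicate 1 (0.0343), 2 (0.0358) or 3 (0.0448), or unstimulated replicate 1 (0.0294) or 3 (0.0296), and its range over all camera alternatives was 0.0294 to 0.224. The 5 higher members were Lif (3.61 ± 0.12), Il15 (3.35 ± 0.08), Csf1 (1.66 ± 0.13), Il27 (0.84 ± 0.06) and Tgfb1 (0.20 ± 0.05). Il12a had 65 reads with CpG and 1 with poly(I:C), a ratio of 47.3 (8.2 to 1900).

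Chemokines split into 7 higher and 8 lower, with a median of -0.05 and a mean of 0.09 that turned to -0.07 with library totals, and camera pointed down and fry up. Cxcl10, Cxcl9 (2.76 ± 0.05) and Ccl5 (0.95 ± 0.05) were higher with poly(I:C), and Ccl3 (-3.42 ± 0.06) and the neutrophil attractant gene Cxcl2 (-2.84 ± 0.07) higher with CpG. NF-kB targets split into 12 higher and 16 lower of 36, or 17 lower adjusted over the list alone (camera adjusted p = 0.193), with Nfkbiz lower (-3.44 ± 0.06) and Nfkbie higher (1.33 ± 0.05). Maturation genes were higher in 12 of 21 cases and lower in 5 (camera adjusted p = 0.0965). The list was called with library totals (adjusted p = 0.0365) and at a mean CPM of at least 5 (0.0448), with a range over all camera alternatives of 0.0365 to 0.214. Cd86 was higher by 0.83 ± 0.05 and Cd40 did not pass (-0.07 ± 0.06, adjusted p = 0.314; -0.24 and called with library totals). Ccr7 stood at the threshold (0.17 ± 0.07, adjusted p = 0.05), and its call was lost with DESeq2, a replicate block (0.17), thinning, library totals (0.01) or without any 1 of the CpG or poly(I:C) libraries (0.12 to 0.20).

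MHC class I genes were higher with poly(I:C) in 17 of 21 cases and lower in 2 (camera adjusted p = 2.85e-06), with Tapbpl up by 1.84 ± 0.07 and Tap2 by 1.71 ± 0.05. MHC class II genes were higher in 11 of 16 cases (camera adjusted p = 0.00833, and adjusted p = 0.225 with an estimated correlation), with H2-DMa up by 1.53 ± 0.07 and Ciita by 1.27 ± 0.06. Apoptosis genes were higher in 19 of 26 cases and lower in 4 (camera adjusted p = 0.000298), with Tnfsf10 up by 3.13 ± 0.20 and Mlkl, which executes necroptosis, by 2.59 ± 0.08, while Bcl2l1 was lower (-1.11 ± 0.05). Cholesterol synthesis genes were lower in 21 of 24 cases and higher in 1 (camera adjusted p = 4.29e-07), with Dhcr7 (-1.40 ± 0.08) and Hsd17b7 (-1.16 ± 0.06) lowest. Genes of cDC1 identity were higher in 14 of 26 cases, or 15 adjusted over the list alone, and lower in 7 (camera adjusted p = 0.129), with Tlr11 up by 2.49 ± 0.20 and Tlr3 by 2.10 ± 0.07. ER stress genes were lower in 16 of 21 cases and higher in 1, or 2 adjusted over the list alone (camera adjusted p = 0.00483, and adjusted p = 0.152 with an estimated correlation), with Dnajb9 (-0.72 ± 0.11) and Asns (-0.66 ± 0.08) lower. Cell cycle genes were lower in 22 of 40 cases and higher in 9 (camera adjusted p = 0.0383, and adjusted p = 0.0978 with an estimated correlation). That call was lost without CpG replicate 1 (mean -0.13, adjusted p = 0.0585) or poly(I:C) replicate 2 (mean -0.12, adjusted p = 0.0581), against a mean of -0.13 with all libraries and a range of adjusted p over all camera alternatives of 0.027 to 0.0978. Beside these lists, cDC2 markers were lower with poly(I:C) in 4 of 4 cases (camera adjusted p = 0.008, and adjusted p = 0.094 with an estimated correlation), and summed to 58.9 ± 2.66 (SD) CPM by library totals against 131.1 ± 2.88 (SD) with CpG.

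No call was made for the other lists between the ligands. Pattern recognition genes were higher in 18 and lower in 10 of 33 cases, with Irf1 and Nod2 both up by 2.08. SOCS family genes split into 3 and 3, with a median of 0.07, a mean of -0.11 and a downward fry direction. AP-1 genes were higher in 8 and lower in 15 of 26 cases, or 16 adjusted over the list alone, with Ier3 lower (-3.21 ± 0.08) and Fos higher (1.85 ± 0.12). Glycolysis genes were higher in 10 and lower in 4, led by Hk3 (2.29 ± 0.08), and oxidative phosphorylation genes were 5 higher and 5 lower, or 4 lower adjusted over the list alone, with a mean of 0.01 that turned to -0.15 with library totals. Ribosomal protein genes were 1 higher and 4 lower, or 3 adjusted over the list alone. Antioxidant genes were lower in 9 and higher in 3, with the ferritin gene Fth1 lower (-1.17 ± 0.05) and Irg1 higher (3.45 ± 0.05). Lysosome genes were 10 higher and 8 lower, with a mean of 0.07 that turned to -0.09 with library totals, and 1 histone was lower. Macrophage markers were 5 higher and 7 lower, with Csf1r down (-1.96 ± 0.14), T cell genes 2 higher and 1 lower, plasmacytoid dendritic cell genes 3 of 4 higher, and stromal genes 1 higher and 1 lower, with a median of -0.01 against a mean of 0.35 and Cdh5 higher by 3.68 ± 0.08. Ms4a1 was lower (-0.78 ± 0.28) and Klrk1 higher (1.08 ± 0.06). Library totals moved the median of all genes by -0.16 (2431 higher, 4942 lower, 33% upward instead of 50.9%).

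**Figure D2:**
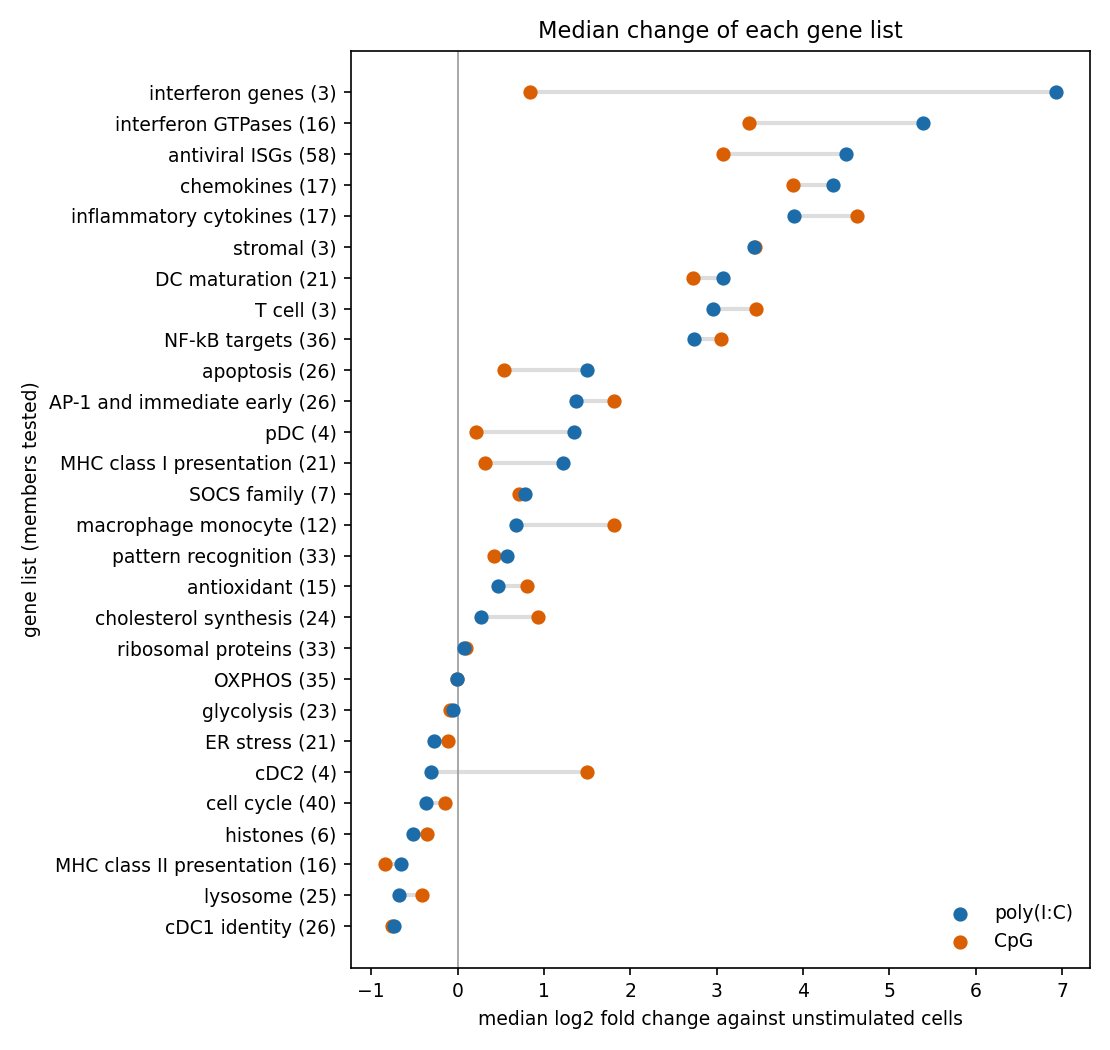
Median log2 fold change against unstimulated cells (horizontal axis) of the 28 tested gene lists under poly(I:C) and CpG, with genes at 0 reads set to their bounds and the number of members tested in brackets. Interferon-induced GTPases had medians of 5.39 with poly(I:C) and 3.37 with CpG, and inflammatory cytokines 3.89 and 4.62.

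Across both comparisons with unstimulated cells, most changes ran the same way, while a smaller set ran in opposite ways. Both ligands raised 3026 genes, where independent calls would share 1490, and both lowered 3180, against 1566.1. Of those raised by both, 1244 were higher with poly(I:C), 756 higher with CpG and 1026 did not pass the direct test. Hopx, a homeodomain-related regulator, rose with poly(I:C) (4.32 ± 0.17) and fell with CpG (-1.14 ± 0.36), and so did the chemokine receptor gene Cxcr4 (1.40 ± 0.15 and -2.18 ± 0.24) and the serotonin receptor gene Htr7 (1.98 ± 0.07 and -1.55 ± 0.09). The fall of Hopx was between low levels, from 1.21 CPM (57 reads) in unstimulated cells to 0.54 CPM (19 reads) with CpG. Clec4a2, a lectin gene, fell with poly(I:C) (-1.73 ± 0.11) and rose with CpG (1.05 ± 0.08).

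In all, 637 genes changed in opposite directions, 382 higher with poly(I:C) and lower with CpG and 255 the reverse, and all 637 also passed the direct test between the ligands. Of these, 31 changed at least 2-fold in both. A further count of 530 genes rose at least 2-fold with poly(I:C) and stood at least 2-fold above CpG, and 296 did the reverse. The fold changes of the ligands had a covariance of 1.584 across genes, against 0.0079 in 30 simulated data sets with unchanged groups and the same controls, and r was 0.816 against 0.426. Genes of the same sign made up 79.6%, against 64.8% in the simulations. The 3 unstimulated libraries served both comparisons and were not divided between them, since 2 libraries for each would be needed, so part of the excess in shared calls may come from the controls.

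**Figure D3:**
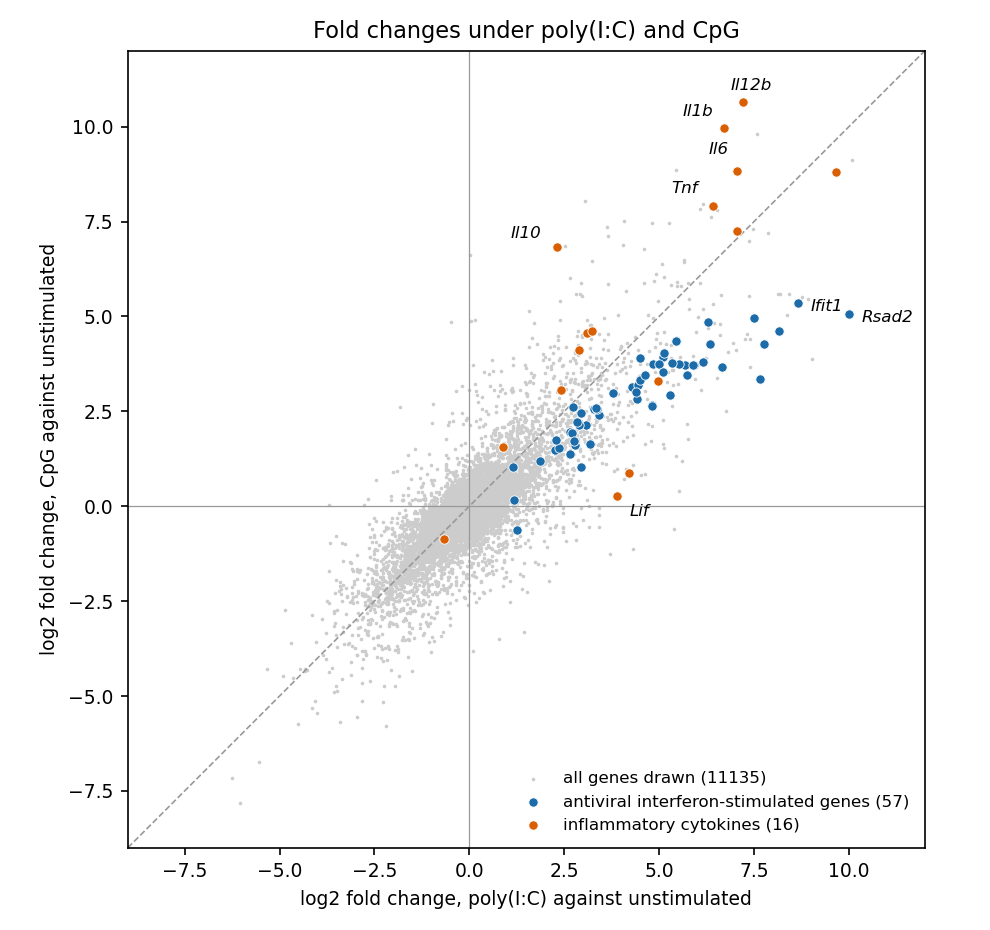
Log2 fold change with poly(I:C) (horizontal) and CpG (vertical) against unstimulated cells for 11135 genes with over 3 reads in every group, leaving out 147, and a dashed line where both are equal. The 57 antiviral genes drawn lie mostly below the line and cytokines such as Il12b (7.20 with poly(I:C), 10.65 with CpG) above it.

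With an estimated correlation in place of the preset value, 10 of the 17 list calls held for poly(I:C), 7 of 16 for CpG and 5 of 10 between the ligands. For poly(I:C) these were antiviral genes, GTPases, cytokines, chemokines, NF-kB targets, maturation, MHC class I, pattern recognition, cell cycle and apoptosis. For CpG they were antiviral genes, GTPases, cytokines, chemokines, NF-kB targets, maturation and cholesterol synthesis. Between the ligands they were antiviral genes, GTPases, MHC class I, cholesterol synthesis and apoptosis. Adjusted p of these kept calls with an estimated correlation was 0.0124 to 0.0491 for poly(I:C), 0.0241 to 0.029 for CpG and 0.0253 to 0.0264 between the ligands. The smaller camera values given above for these lists rest on the preset correlation. Where no count adjusted over the list alone is given, it equalled the count over all genes.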

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

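The test in this part was chosen before its result was seen. Reads that fell on more than 1 gene, which no comparison uses, made up 0.33% of the reads in the files of the poly(I:C) libraries (SD 0.01, n = 3). In the unstimulated libraries their share was 0.283% (SD 0.0153) and with CpG 0.307% (SD 0.0115). This share was singled out because it is a signal outside the gene counts that lay above the level of the unstimulated cells.

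Reads on no gene made up 58.49% to 59.37% of every library, and a candidate explanation is counting on 1 strand of a library that does not mark strand. If so, genes lying wholly within exons of an expressed gene on the other strand would take up reads at about that gene's rate. Their median ratio of reads per kb to the host gene was 1.606 (bootstrap interval 0.233 to 2.995) over 7 such genes, 5 of them above 0.5. This keeps the explanation open without deciding it, since the interval spans 0.5, the genes are few and the annotation used for counting is not given. The share averaged 58.8% in unstimulated cells, 59.3% with CpG and 58.8% with poly(I:C), and no biological explanation was tested.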

How the results depend on the processing

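Scaling by library totals, and thinning for lists, overlap, covariance and opposite changes, were chosen after seeing the data. Of 231 recomputed counts and covariances, 201 stayed within the limits set for them and 30 moved. Of 1332 list results 1258 were unchanged in direction and call, 41 gained a call, 30 lost it and 3 reversed. Of 3491 results of named genes 3467 were unchanged, 20 lost a call, 1 gained it and 3 reversed. Many of these genes were picked for large changes without overlap between libraries, so their stability does not stand for all genes. Every alternative planned was run. The cause of changes with library totals, fry and an estimated correlation was not tested. Those of glmTreat and the fold limit follow from the stricter threshold. The covariance moved with other count filters and on leaving out any library, and the cause was not tested.

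Against a fold of 2, glmTreat called 1353 higher and 977 lower for poly(I:C), 1084 and 1038 for CpG, and 635 and 294 between them. Library totals gave 2447 and 6764 for poly(I:C), 4942 lower between the ligands, and 1786 raised and 4907 lowered by both. Among the named genes library totals also reversed Irf4 (-0.04), Rpl19 (-0.12) and Rpl27 (-0.01) under poly(I:C). Of all genes called with both scalings, 346 of 7063 had the opposite sign under poly(I:C), 2 of 6957 under CpG and 0 of 5608 between the ligands. With a fold of at least 2, 1022 were raised and 982 lowered by both and 31 changed oppositely. The covariance was 1.727 without a filter and 1.25 at a mean CPM of at least 5. An estimated correlation called 10, 7 and 5 lists. With fry 27 lists were called for CpG and 24 between the ligands, and 3 means ran against camera, ER stress with CpG (0.18) and chemokines (0.09) and SOCS family (-0.11) between the ligands.

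Leaving out each library gave 3934 to 4145 higher and 4012 to 4313 lower genes for poly(I:C), 3956 to 4120 and 3948 to 4207 for CpG, and 3054 to 3381 and 2802 to 3399 between the ligands. Shared rises were 2919 to 3007, shared falls 3010 to 3152, opposite changes 562 to 614 and covariances 1.614 to 1.652, with 17, 16 and 9 to 11 lists called. With the replicate number as a block the counts were 4115 and 4259, 4131 and 4153, 3292 and 3192, with 3042, 3173 and 641 shared or opposite, a covariance of 1.584 and 17, 16 and 10 lists. The number is weak evidence of pairing, since after removing group means libraries of a number correlated at -0.122 to 0.239 and only 2 of 9 pairs exceeded 0.1. Unstimulated and CpG libraries of a number correlated at 0.089, 0.239 and 0.149, against -0.164 to 0.014 for other numbers. Deviations from a group mean cancel out over its libraries, so positive values for a number push the others down. The values for other numbers are therefore no separate evidence of pairing. Pairs of a number with a poly(I:C) library correlated at -0.122 to -0.036. A pairing of unstimulated with CpG libraries thus stays open. Thinning to the smallest library gave 3909 and 4043, 3877 and 3846, and 3102 and 2932 genes, so depth costs some calls.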

Other observations

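The gene groups of the first 2 paragraphs and the tests of identity genes and of the 11 lower cytokine genes were chosen after their results were seen. Scaling by library totals and the thinning of lists were added after the data, but before their own results, were seen, and the other tests were chosen before. Of 32 tested cytokine receptor genes, 22 rose and 6 fell with poly(I:C), and 18 rose and 9 fell with CpG. Ifnlr1, the receptor for interferon lambda, rose by 6.84 ± 0.21 with CpG and 2.51 ± 0.45 with poly(I:C). Il10ra rose by 3.41 ± 0.07 with poly(I:C) and 2.93 ± 0.07 with CpG, and the interferon gamma receptor gene Ifngr1 fell (-0.45 ± 0.04 and -1.65 ± 0.05). Il2rg, the shared receptor chain of several cytokines, rose by 2.88 ± 0.07 and 1.09 ± 0.07, and Lifr, the receptor for Lif, fell (-0.51 ± 0.08 and -3.14 ± 0.10).

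The Notch ligand gene Dll1 rose by 6.95 ± 0.19 with poly(I:C) and 4.30 ± 0.28 with CpG, while Jag2 fell (-1.92 ± 0.09 and -1.80 ± 0.08). The prostaglandin receptor gene Ptger4 rose by 2.88 ± 0.08 and 2.73 ± 0.07, while Ptger2 fell (-2.54 ± 0.13 and -2.54 ± 0.12), as did Alox5ap, which serves leukotriene synthesis (-2.33 ± 0.07 and -3.69 ± 0.07). The tryptophan-degrading enzyme genes Kynu (2.62 ± 0.06 and 0.71 ± 0.06) and Ido1 (4.90 ± 0.19 and 3.52 ± 0.22) rose with both. The migration receptor gene S1pr2 rose with poly(I:C) (1.20 ± 0.07) and fell with CpG (-1.08 ± 0.08).

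Antiviral genes were higher and inflammatory cytokines lower with poly(I:C) than with CpG, with list means of 1.54 and -0.92, although the cytokine list was not called (camera adjusted p = 0.0591). Thinning every library to the smallest total gave an antiviral mean of 1.54 ± 0.01 (SE from replicates, 0.13 over members). Library totals in place of TMM gave 1.38 ± 0.01, and both lay past the bound of 1. Neither was likely to fall short of it, since thinning hardly moves a mean of normalised fold changes and library totals moved the median of all genes by only -0.16. The antiviral difference is thus larger than the shift between these scalings, while thinning is no real test of depth. The cytokine means of -0.90 ± 0.058 with thinning and -1.08 ± 0.053 with library totals do not decide about depth or scaling for that list. Its members went both ways, with an SE over members of 0.57 and 0.59. The thinned mean was -0.65 over the 15 members that passed the count filter after thinning. In a thinned fit that kept the genes of the main test, all 11 cytokine genes called lower were again called lower. This was nearly fixed in advance, since the genes were chosen for that call, and it does not test depth. Of these genes 10, all but Tnfsf15 (-0.20 ± 0.06), lay below the median of all genes by more than 0.16, beyond 2 SE. The value of 0.16 is the largest shift between the scalings compared, whose factors move all genes alike. The choice between these scalings thus does not account for those 10 differences, though the genes were picked as lower in these same libraries. A difference in how the cells respond to the ligands may account for both patterns and stays open as a hypothesis, beside a difference in dose, since each ligand was given at 1 dose whose unit is in doubt.

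Most cDC1 identity genes fell with both ligands, and a candidate explanation is cells of another type in the stimulated cultures. Such cells would lower all identity genes together, yet 5 of them rose at least 2-fold with poly(I:C) and 5 with CpG, namely Cd8a, Fgl2, Gcsam, Ly75 and Xcr1 in both. By library totals, macrophage and monocyte markers, 12 of 16 of which had a mean CPM of at least 1, summed to less with poly(I:C) and CpG than in unstimulated cells (262.3 and 412.5 against 607.4), yet 8 of the 12 tested rose with each ligand and the list was called upward by camera on that scale (adjusted p = 0.044 and 0.0296, against 0.23 and 0.166 with TMM, and adjusted p = 0.291 and 0.221 with an estimated correlation). Markers of cDC2 cells rose in 4 of 4 tested cases with CpG (131.1 against 64.64, and 58.9 with poly(I:C)), and stromal markers summed to more (110.9 and 13.25 against 6.407), mostly through Cdh5 (109.6 and 9.602 against 6.167). Most listed cDC2 and stromal markers had too few reads to be tested, and Cd209a, Clec10a and Col3a1 had none in any group. The 5 rising identity genes could not have risen through dilution by cells that lack them. Their rise does not tell what lowered the other members, and this test was chosen after it was seen. Dilution by cells that lack these genes would lower the falling members alike. Yet only 11 of the 18 that fell did so at least 2-fold with each ligand. With poly(I:C), for example, Tlr3 fell by -0.37 ± 0.07 and Cxcr3 by -6.05 ± 0.23. These unlike falls argue against such dilution as the only cause for the falling members. Other cells as a part of the cause and regulation of single genes by the ligands both stay open.

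The 10 splits of the 6 libraries of a comparison are too few for a share under 0.05. The real split, the only 1 of the 10 to give as many, called 8179 genes for poly(I:C), 8103 for CpG and 6692 between the ligands by edgeR on those 6 libraries, and the highest other split 0. At an unadjusted p under 0.05 the real splits gave 8332, 8311 and 7054 genes and the highest other splits 47, 72 and 99. For lists the real splits called 16, 15 and 11 and the other splits 10 to 14, 7 to 11 and 4 to 8. The number of lists called at the preset correlation thus separated the real groups only weakly from mixed ones. Among 100 drawn splits of the 9 libraries, 1 gave as many genes changed the same way (6206, highest other 3863). For opposite changes 2 gave as many (637, highest other 1406), and for the covariance 1 gave as large a value (1.584, highest other 0.82). Each share was under 0.05. Splits that mix the groups count the differences between groups as spread, so calls of genes in them were unlikely from the start. These shares therefore show that the groups differ, and do not test whether shared controls account for the overlap. The split with 3863 and 1406 kept the 3 groups whole and took a stimulated group as the control, which points to the structure of the samples.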
